A study of Mus musculus with 6 samples.

How the data were processed

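Expression was measured by microarray in tibialis anterior, a fast muscle of the lower hind limb, from 6 male mice aged 8 weeks. Of these, 3 lacked the transcription factor ATF4 in skeletal muscle (ATF4 mKO) and 3 were littermate controls. All mice had been fasted for 24 h before the muscles were taken. Per the labels' protocols, total RNA was extracted with TRIzol, 50 ng was amplified to cDNA with a SPIA-based kit, and the fragmented, biotin-labelled cDNA was hybridised to 1-colour arrays.

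The deposited table holds log2 expression values, 1 per array feature and mouse. Its scale was read from the values, which lay between 1.63 and 13.0 with no missing entries, and was not stated in the sources used here. Per the submitters' processing notes, GCOS and RMA were used with the mouse build mm9; versions, the RMA software and the feature annotation were not given in the sources used here. RMA corrects background, quantile-normalises the arrays and summarises the probes of a feature, so a log2 fold change is the difference of such summaries and is compressed near the background. The deposited columns had medians of 5.84 to 5.91. Scanner files were not used here, so the call of a feature as above background could not be made and a level below the median of all features is named as such. The number of arrays limits the precision.

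Features were named from the platform annotation of the array, with symbols updated through the Entrez identifier. Of the 16755 features, 14996 had 1 gene symbol, 1019 had several and 740 had none; 14941 of those with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6. That table was used for names and for the order of neighbouring genes only, because its build differs from that of the data, so no coordinates are given. No gene was named from a feature with several symbols. For gene lists, a gene was represented by its feature with the highest mean; among the listed genes, 1 had more than 1 feature, Rgs5, whose features had log2 fold changes of -0.070 and -0.027.

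The comparison was ATF4 mKO against control over all 16755 features, fitted with limma 3.58.1 (lmFit and eBayes with default settings, R 4.3.3) and group as the only term. P-values were adjusted by Benjamini-Hochberg and the threshold was an adjusted p of 0.05. Errors on fold changes are limma's moderated standard errors and intervals are at 95%; percentages of control are back-transformed from differences of mean log2 values. The titles number the mice 1 to 3 in each group but nothing states that the numbers pair them. The mice are separate animals.

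The 28 gene lists and the rule for the genes to be named were fixed before the data were examined. They comprised 19 lists of pathways and 9 of markers of cell types that a muscle sample can hold, with 410 distinct genes, of which 331 had a feature of their own. List shifts were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 28 lists. Within each list, p-values were also adjusted over the list alone. The rule named Atf4, up to 15 features per direction that passed the threshold with no overlap between the groups, filled up to 10 per direction with the smallest unadjusted p, a set of 10 genes chosen in advance, and up to 4 members of each list with the smallest p. Of the genes chosen in advance, Trim63 and Eif4ebp1 had no feature of their own and were not analysed here.

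Alternatives were the replicate number as a block, quantile normalisation, median centring, leaving out the lowest 33.3% or the lower 50% of features by mean level, features with 1 symbol only, an intensity trend with robust moderation, no moderation, array weights, other thresholds, other list tests, and leaving out each mouse. An intensity trend in camera was added after the data were seen. No 2 arrays were identical; their correlations ran from 0.983 to 0.991. The fit was tested on simulated data drawn for the 16755 features with 3 mice per group and 200 changed features. It called 35.7% of features changed by 0.5 on the log2 scale, 91.9% of those changed by 1 and 98.8% of those changed by 2, and 5.40% of its calls were false. Camera called all simulated lists of 20 genes shifted by -0.4. The simulated genes were drawn independently and 200 were changed, whereas the data gave 2 calls. The synthetase list had 16 genes, a median of -0.27 and an estimated correlation of 0.127. These shares may therefore overstate what could be detected here.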

Results

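The data were log2 expression values of 16755 array features in tibialis anterior muscle of 3 ATF4 mKO mice and 3 littermate controls, all fasted for 24 h. ATF4 is a basic leucine zipper transcription factor that is translated when the initiation factor eIF2 is phosphorylated, as in amino acid shortage and endoplasmic reticulum stress. The comparison addressed which muscle mRNAs depend on ATF4 during fasting, a state in which muscle protein is broken down. Values are given as the mean ± SD of 3 mice on the log2 scale.

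The Atf4 signal (array feature 6831994) was lower in every ATF4 mKO muscle than in any control. It averaged 8.73 ± 0.06 (SD, n = 3) in control muscle and 6.92 ± 0.17 (SD, n = 3) in ATF4 mKO muscle. The log2 fold change was -1.80 ± 0.10 (SE), so that 28.7% of the control signal remained, with an adjusted p of 0.00268 in limma. Which exons the knockout removes and which the feature covers is not known here, so this share is of the feature's signal and may mix deleted and retained exons. Cells other than muscle fibres keep the gene and may add to the remaining signal. An exact two-sided permutation test of the 6 values gave p = 0.10, the smallest that 3 against 3 mice allow. Without variance moderation the adjusted p was 0.192; over all 15 alternatives it ran from 0.000378 to 0.192.

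Apart from Atf4, the mRNAs with the smallest p-values encoded enzymes that charge tRNAs with amino acids and a partner transcription factor of ATF4. Yars, the tyrosyl-tRNA synthetase (feature 6917283), fell from 7.44 ± 0.05 to 6.60 ± 0.05 (SD, n = 3), to 55.9% of control, with an adjusted p of 0.0337. Cars, the cysteinyl-tRNA synthetase, stood at 55.6% of control and Cebpg, a C/EBP family member that dimerises with ATF4, at 52.0%. Their log2 fold changes were -0.85 ± 0.09 (SE) and -0.94 ± 0.10 (SE), and both had an adjusted p of 0.0588, short of the threshold. In total, 2 features passed limma's threshold, Atf4 and Yars, both lower; no feature passed it in the higher direction. At an unadjusted p under 0.05 there were 518 features, 286 lower and 232 higher, where 838 would be expected with no effect. Yars lost its call when any of the 6 mice was left out, with adjusted p-values of 0.127 to 0.244 and log2 fold changes of -0.86 to -0.81. The call was also lost with the replicate number as a block, with median centring and without variance moderation. Over the 15 alternatives the adjusted p of Yars in limma ran from 0.00526 to 0.330, and 6 passed the threshold. Leaving out the lower 50% of features by mean level gave 7 calls, all lower.

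**Figure D1:**
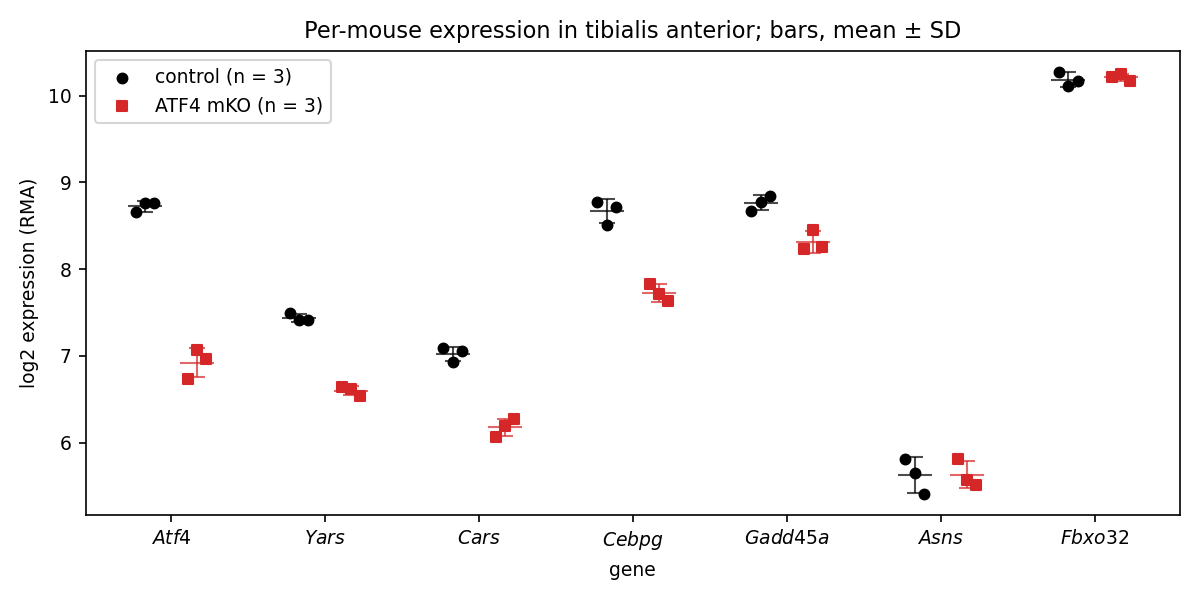
Log2 expression (vertical axis) of 7 genes in each mouse, with control muscles as black circles and ATF4 mKO muscles as red squares; bars show the mean and SD of 3 mice. The Atf4, Yars, Cars, Cebpg and Gadd45a values of the 2 groups do not overlap, whereas those of Asns and Fbxo32 do. The Asns feature lies below the median level of all features.

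Of the 10 genes named in the lower direction, 6 were cytosolic tRNA synthetases and 8 lay above the median level of all features. Besides those given above they were Mars1, Gars, Iars and Nars, with Nol12 and Cetn1 as the 2 members below the median level. Nol12, a nucleolar protein gene, had a log2 fold change of -0.67 ± 0.09 (SE, adjusted p = 0.211) at percentile 42.9 of the mean level; in 8 of the other 9 splits of the 6 mice a feature below the median level reached a p as small. The other, Cetn1, a centrin gene, had -0.69 ± 0.10 (SE, adjusted p = 0.354). The 10 genes named in the higher direction were Rps15, H2bu2, Hrh2, Gpr84, Tbrg3, Dcakd, H2-M10.3, Dyrk2, Gm5828 and 3110009E18Rik. None passed the threshold, with adjusted p-values of 0.502 and above, and their log2 fold changes ran from 0.38 to 0.66. Of these 10, 8 lay below the median level of all features; the Rps15 feature stood at percentile 12.1 and that of H2bu2, a histone gene, at percentile 2.34. Nol12 and Tbrg3 lie 30 and 38 measured genes from Atf4 on its chromosome. The groups did not overlap at 7.78% of all features, where chance gives 10% for 3 against 3 mice.

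Camera called the cytosolic tRNA synthetase list lower at its preset correlation but not with an estimated correlation (adjusted p = 0.166, range over the 16 alternatives 5.86e-19 to 0.166). Of the 16 measured, 1 (Yars) passed the threshold over all features and 8 passed it when adjusted over the list alone, all of them lower. All 16 are named here, some of them chosen after their values were seen. The 8 were Cars, Yars, Mars1, Iars, Gars, Lars, Nars and Tars, which charge tRNAs for cysteine, tyrosine, methionine, isoleucine, glycine, leucine, asparagine and threonine. Their levels in ATF4 mKO muscle were 55.6% to 75.6% of control, and in all 8 every ATF4 mKO mouse lay below every control. Nars went from 10.14 ± 0.02 to 9.71 ± 0.03 (SD, n = 3), and Gars from 8.72 ± 0.02 to 8.19 ± 0.05 (SD, n = 3). The other 8, namely Farsb, Hars, Qars, Rars, Kars, Wars, Farsa and Vars, stood at 90.9% to 105% of control. Kars, the lysyl-tRNA synthetase, had a log2 fold change of -0.0012 with a 95% interval of -0.17 to 0.17, and Wars, for tryptophan, had 0.0019 with an interval of -0.17 to 0.17.

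The median log2 fold change of the synthetase list was -0.27, or 82.9% of control, and camera called it lower with an adjusted p of 6.00e-16. With an estimated correlation of 0.127 between its members, its camera p was 0.00591 and its adjusted p the 0.166 given above; fry, which does not compare the list with other genes, gave an adjusted p of 0.00641. The mean of the 16 genes per mouse was 7.80 ± 0.03 in controls and 7.49 ± 0.04 (SD, n = 3) in ATF4 mKO muscle, with an exact permutation p of 0.10, the smallest possible.

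**Figure D2:**
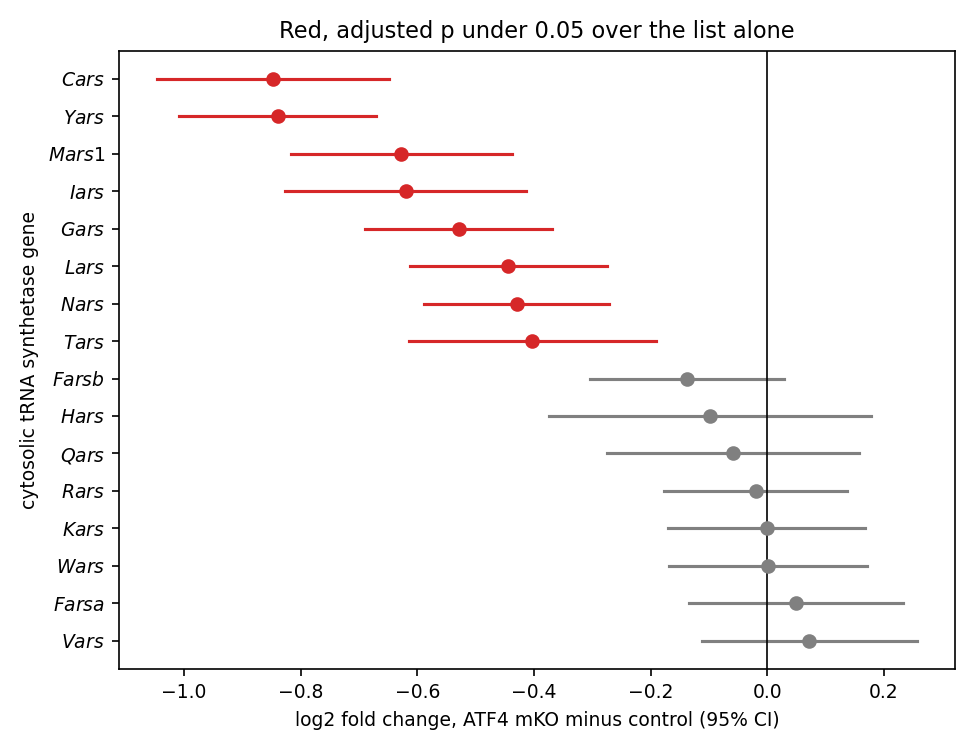
Log2 fold change, ATF4 mKO minus control, of the 16 measured cytosolic tRNA synthetase genes (points) with 95% intervals from limma (lines). Red marks the 8 genes past an adjusted p of 0.05 over the list alone, from -0.85 to -0.40; the other 8, in grey, lie between -0.14 and 0.07.

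In the integrated stress response list, 2 of 15 members fell when adjusted over the list alone, Cebpg and Atf5, and none passed over all features. Atf5, a transcription factor related to ATF4, stood at 73.7% of control (log2 fold change -0.44 ± 0.08, SE; adjusted p = 0.753 over all features). Ddit3, which encodes CHOP, had -0.24 with a 95% interval of -0.47 to 0.0018. Trib3 had 0.03 (-0.20 to 0.27), and Fgf21, a secreted hormone, 0.0002 (-0.23 to 0.23). The list's median was -0.048 and its camera adjusted p was 0.00832; the adjusted p was 0.235 with an estimated correlation (range over the 16 alternatives 4.28e-05 to 0.235). Without 1 mouse the median ran from -0.15 (without ATF4 mKO mouse 2; -0.11 without ATF4 mKO mouse 1) to -0.034 (without control mouse 3), and the call was lost without control mouse 2 or ATF4 mKO mouse 3.

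None of the 11 measured amino acid synthesis genes passed over all features or over the list alone. Mthfd2, a mitochondrial folate enzyme, came nearest with -0.35 ± 0.09 (SE, adjusted p = 0.0535 over the list alone), followed by Gpt2, an alanine transaminase, with -0.23 ± 0.09 (SE). Asns, the asparagine synthetase, had 0.0013 with a 95% interval of -0.29 to 0.29. Psat1, an enzyme of serine synthesis, had -0.24 with an interval of -0.67 to 0.19. Both lay below the median level of all features, at percentiles 42.2 and 16.4, so low signal may hide a fall. The median was -0.069, and camera called the list lower with an adjusted p of 0.00832 (adjusted p = 0.235 with an estimated correlation, range 0.00588 to 0.235). Without 1 mouse the median ran from -0.14 (without ATF4 mKO mouse 2; -0.11 without control mouse 3) to -0.067 (without control mouse 1), and the call was lost without control mouse 1 or ATF4 mKO mouse 3. It was also lost without the lowest 33.3% of features (median -0.027, adjusted p = 0.0767). Among 11 amino acid transporters none passed. Slc38a2, a neutral amino acid transporter, had -0.34 ± 0.09 (SE, adjusted p = 0.0774 over the list alone) and Slc7a1, a cationic amino acid transporter, -0.27 ± 0.11 (SE). The transporter median was -0.0047, with a camera adjusted p of 0.171. The list was called lower without the lowest 33.3% of features (median -0.094, adjusted p = 0.0388, range over the 16 alternatives 0.0388 to 0.673), and its median ran from -0.12 without control mouse 3 to 0.01 without ATF4 mKO mouse 1. Per mouse, the mean shift of the synthetases was lower than that of the synthesis genes by 0.20 ± 0.01 (SE) and than that of the transporters by 0.24 ± 0.04 (SE); each exact permutation p was 0.10, the smallest possible.

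Among 16 endoplasmic reticulum chaperone genes, 14 had values below control but none passed over all features or over the list alone. Hspa5, the main chaperone of this compartment, had -0.12 ± 0.10 (SE) and Dnajb9 -0.26 ± 0.21 (SE). The median was -0.085 and the camera adjusted p 0.0497 (adjusted p = 0.673 with an estimated correlation, range 0.00409 to 0.694). Without 1 mouse the median ran from -0.12 (without ATF4 mKO mouse 2) to -0.016 (without control mouse 2; -0.025 without ATF4 mKO mouse 3), and the call held only without control mouse 1 or ATF4 mKO mouse 2. Of 26 proteasome subunits, 21 had values below control and none passed. Psmd14 had -0.15 ± 0.08 (SE) and Psma1 -0.14 ± 0.10 (SE). Over the 15 alternatives they ran from -0.21 to -0.092 and from -0.20 to -0.045. The proteasome median was -0.047 and its camera adjusted p 0.0457 (adjusted p = 0.673 with an estimated correlation, range 0.00588 to 0.694). Without 1 mouse the median ran from -0.067 (without ATF4 mKO mouse 1) to -0.022 (without ATF4 mKO mouse 3; -0.028 without control mouse 3), and the call held only without ATF4 mKO mouse 1 or 2. These were, with the synthetases, the stress response and amino acid synthesis, the 5 lists that camera called, and all 5 were lower. The other 9 ways to split the 6 mice into 3 and 3 called 1, 6, 0, 1, 4, 4, 0, 4 and 0 lists. Camera thus also called lists in splits that mix the genotypes. Each of these still sets 2 mice of a genotype against 1, so it keeps part of any genotype difference and is no null grouping. Across those 9 splits the smallest unadjusted camera p of the synthetase list was 0.00614, against 2.14e-17 in the real split. The number called was 2 without control mouse 2 or without ATF4 mKO mouse 3 and 9 without ATF4 mKO mouse 2. Over the 16 alternatives the call held in 15 for the synthetases, 12 for the stress response, 11 for amino acid synthesis, 9 for the chaperones and 8 for the proteasome. With an estimated correlation none of the 5 was called. The part of this that correlation accounts for was not separated in any list, the synthetases included. The estimates for the stress response and amino acid synthesis were -0.044 and -0.031, below the preset 0.01. Their unadjusted camera p nevertheless rose from 0.000616 to 0.0216 and from 0.000891 to 0.0252, so this setting changes more than the correlation.

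Of 12 measured muscle atrophy genes, 1 fell when adjusted over the list alone. This was Gadd45a, a stress-induced nuclear protein gene, which went from 8.76 ± 0.09 to 8.31 ± 0.12 (SD, n = 3). Its log2 fold change was -0.45 ± 0.09 (SE), or 73.2% of control, with an adjusted p of 0.0159 over the list alone and 0.964 over all features, and every ATF4 mKO mouse lay below every control. Fbxo32, the ubiquitin ligase atrogin-1, had 0.02 with a 95% interval of -0.15 to 0.20. Cdkn1a, the cell cycle inhibitor p21, had -0.39 with an interval of -1.15 to 0.36, and Foxo1, a forkhead transcription factor, had 0.13. The list's median was -0.033 and its camera adjusted p 0.596. Without 1 mouse the median ran from -0.090 (without control mouse 1) to 0.056 (without ATF4 mKO mouse 3), and the list was called lower without ATF4 mKO mouse 2 (median -0.081, adjusted p = 0.0303, range over the 16 alternatives 0.0303 to 0.867).

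The remaining pathway lists were not called with all 6 mice and the settings above, and none of their members passed over all features or over the list alone. Their median log2 fold changes are given with the range without 1 mouse in brackets. They were -0.042 (-0.047 to -0.013) for autophagy and lysosome genes, 0.012 (-0.022 to 0.059) for fatty acid oxidation, 0.047 (0.0045 to 0.048) for oxidative phosphorylation and 0.037 (0.011 to 0.074) for glycolysis and glycogen. They were -0.037 (-0.071 to 0.0076) for growth signalling, 0.053 (0.0066 to 0.11) for neuromuscular junction genes, 0.022 (0.011 to 0.037) for fast fibre and 0.040 (-0.059 to 0.11) for slow fibre contractile genes. Clock genes had 0.059 (0.035 to 0.096) and immediate early and heat shock genes 0.052 (-0.0069 without control mouse 1 to 0.098 without control mouse 3). Polyamine metabolism had 0.025 (-0.083 without control mouse 1 to 0.10 without control mouse 2). Glucocorticoid response had -0.015 (-0.13 without control mouse 3 to 0.12 without ATF4 mKO mouse 3). The mean and the test of the glucocorticoid list had the opposite sign to its median, as did the mean of the neuromuscular junction list. Autophagy and growth signalling genes were called lower without ATF4 mKO mouse 2 (adjusted p = 0.0378, range 0.0378 to 0.908, and 0.0167, range 0.0167 to 0.694). Slow fibre genes were called higher without ATF4 mKO mouse 1 (adjusted p = 0.0115, range 0.0115 to 0.885). Oxidative phosphorylation genes were called higher with an intensity trend in camera and all 6 mice (adjusted p = 0.0491), and without ATF4 mKO mouse 3 (adjusted p = 0.0434, range 0.0434 to 0.770). At an unadjusted p under 0.05 were 3 of their members: Musk, a kinase of the neuromuscular junction, with -0.43 ± 0.12 (SE), Fbp2, the muscle fructose bisphosphatase, with -0.30 ± 0.10 (SE), and Cyc1, a cytochrome of the respiratory chain, with 0.20 ± 0.08 (SE).

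None of the 9 cell type marker lists was called with all 6 mice, the lowest camera adjusted p being 0.113, for smooth muscle. Median log2 fold changes, with the range without 1 mouse in brackets, were -0.040 (-0.085 to 0.0071) for satellite cells, 0.055 (0.035 to 0.066) for endothelium, 0.051 (0.033 to 0.095) for fibroblasts and -0.059 (-0.079 to -0.019) for adipocytes. They were 0.076 (0.013 to 0.14) for macrophages, 0.058 (0.027 to 0.11) for smooth muscle, -0.030 (-0.088 to 0.057) for Schwann cells and 0.066 (0.012 to 0.15) for tendon. Erythroid cells, resting on 3 genes, had 0.082 (-0.0025 without control mouse 3 to 0.28 without control mouse 1). Without 1 mouse, 3 lists were called higher: erythroid without control mouse 1 (adjusted p = 0.0408, range 0.0408 to 0.917), smooth muscle without control mouse 3 (0.00793, range 0.00793 to 0.694) and fibroblasts without ATF4 mKO mouse 2 (0.0378, range 0.0378 to 0.694). The mean and the test of the Schwann cell list had the opposite sign to its median. At an unadjusted p under 0.05 were the smooth muscle gene Cnn1 with 0.35 ± 0.11 (SE, adjusted p = 0.124 over the list alone) and the endothelial gene Tie1 with 0.17 ± 0.07 (SE, adjusted p = 0.467 over the list alone). The erythroid gene Slc4a1 had 0.44 with an interval of -0.07 to 0.94. Control mouse 3 stood at 5.91 and the other controls at 6.76 and 6.77. Over the 15 alternatives the value ran from 0.15 to 0.58.

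**Figure D3:**
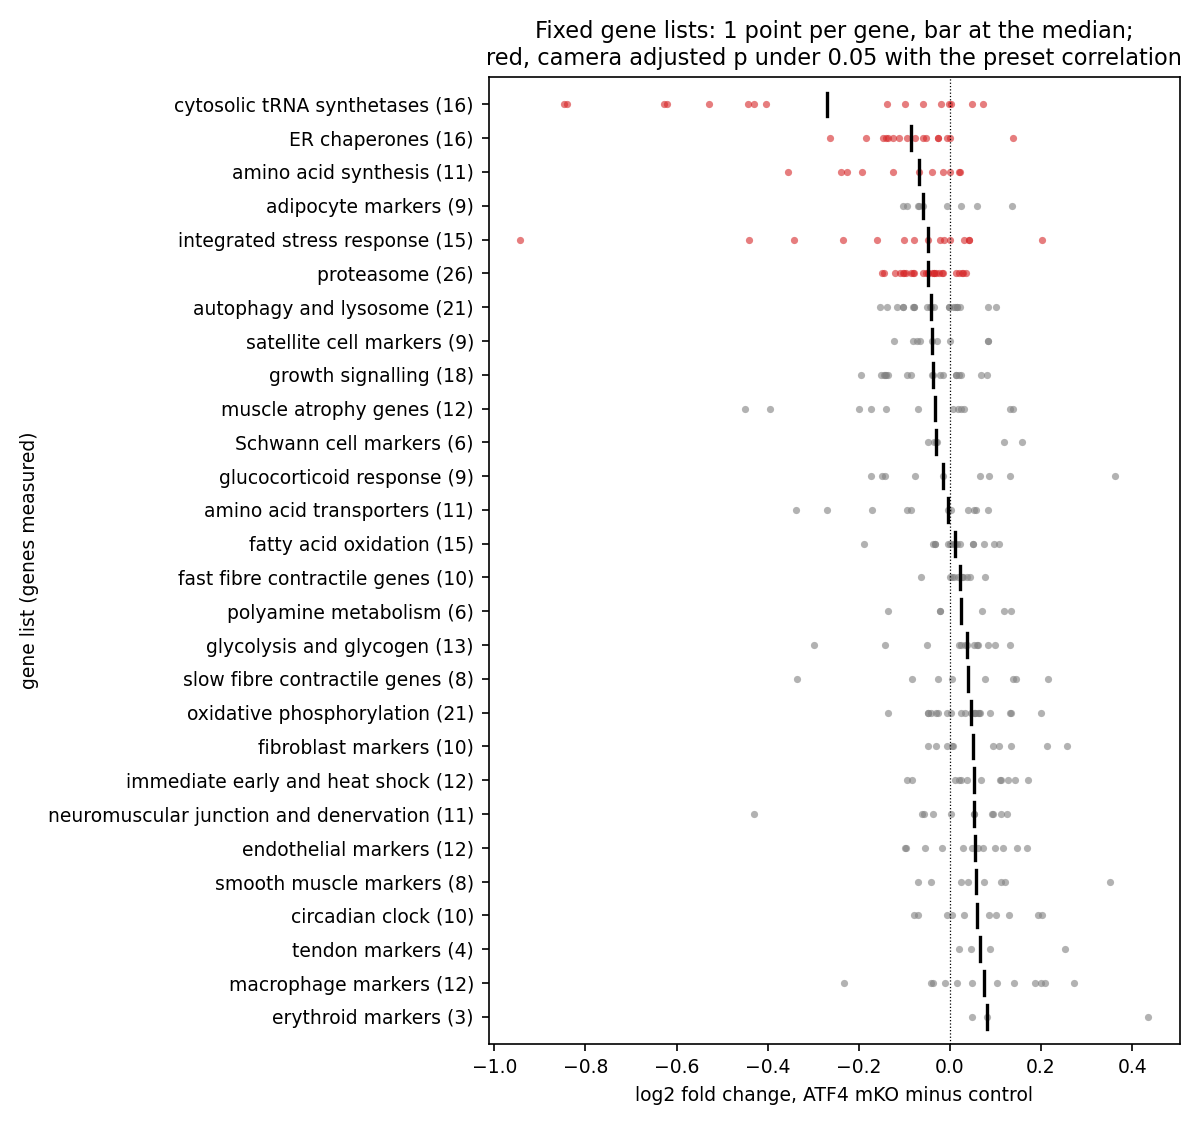
Log2 fold change, ATF4 mKO minus control (horizontal axis), of each measured gene (points) in the 28 lists, with a bar at the list's median and the number of genes in brackets. Red marks the 5 lists that camera called with the preset correlation; the synthetase median of -0.27 stands apart from the other medians, which lie between -0.09 and 0.08.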

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

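The intensity trend in camera was chosen after the results were seen. Atf4 kept its direction under all 15 alternatives, with log2 fold changes of -1.88 to -1.71 (-1.88 to -1.71 without each mouse), and passed the threshold under 14; without variance moderation it was -1.80 with an adjusted p of 0.192 (range 0.000378 to 0.192). The count of changed features, 2, became 0 without variance moderation (limma; 632 at an unadjusted p under 0.05), 1 with median centring, 5 without the lowest 33.3% of features, 7 without the lower 50%, 4 with features of 1 symbol only, 7 with an intensity trend and robust moderation, and 4 at an adjusted p under 0.10. It was 1 without each mouse (range 1 to 1), the call lost each time being Yars. All features called were lower in ATF4 mKO; those added were synthetases, Cebpg and 1 feature shared by Aars and another gene. With the replicate number as a block the count was 1; same-numbered mice had residual correlations of -0.0021, 0.069 and 0.14, and the numbers were not taken to pair the mice. The synthetase list kept its direction under all 16 alternatives (medians of -0.29 to -0.24, also the range without each mouse) and its call under 15; with an estimated correlation its median of -0.27 had an adjusted p of 0.166 (range 5.86e-19 to 0.166). The number of called lists, 5, became 0 with an estimated correlation (camera; 3 at an unadjusted p under 0.05), 1 with fry, 3 with median centring and 6 with an intensity trend, which added oxidative phosphorylation in the higher direction (adjusted p = 0.0491, range 0.0434 to 0.770), and ran from 2 to 9 without each mouse. Some lists not called in the analysis above were called without 1 mouse: lower for muscle atrophy, autophagy and growth signalling genes, all without ATF4 mKO mouse 2, and higher for erythroid, smooth muscle, slow fibre, fibroblast and oxidative phosphorylation genes. Without the lowest 33.3% of features transporters were called lower, and amino acid synthesis lost its call (median -0.027, adjusted p = 0.0767). The chaperones lost theirs with median centring, and the proteasome with median centring and with the replicate block. The cause was not tested. No gene or list called with the report's settings changed sign, and no value called under an alternative had the opposite sign to the reported one; 62 of 2352 alternative values, some of them in lists called under another alternative, changed sign without a call. Background was not measured, so what low signal hides is unknown.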

Other observations

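The tests on the shift of all features and on the neighbours of Atf4, and the split of the mice for the count of changed features, were chosen after the results were seen; the 3 added gene lists, and Eif2s2 as a gene to name, were chosen after their values or those of related genes were seen. Among 24 measured translation initiation factors, 18 had values below control. Eif2s2, the beta subunit of eIF2, had 9.79 ± 0.03 in controls and 9.41 ± 0.07 (SD, n = 3) in ATF4 mKO muscle, 76.5% of control, with an adjusted p of 0.807 over all features. It was asked whether initiation factors other than Eif2s2 may be lower as a group: the remaining 23 had a median of -0.055 and a camera p of 0.0356, but p = 0.360 with an estimated correlation, which leaves this open.

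The genes listed as mitochondrial tRNA synthetases, whose enzymes charge tRNAs in the mitochondrial matrix, gave as a group no sign of the shift of the cytosolic list. Of 15 measured, 7 were below and 8 above control, none passed over the list alone, and the camera p was 0.969. Gars, which was lower, and Kars, at 99.9% of control, were counted on the cytosolic list only. Enzymes that serve both compartments are therefore not covered by this comparison. Among 12 cytosolic ribosomal protein genes the median was 0.019 and the camera p 0.305; 1 of them, Rps15, passed in the higher direction over the list alone (adjusted p = 0.00467), but the list was chosen after Rps15 had been seen, so this adds nothing to its adjusted p of 0.502 over all features. The same holds for Eif2s2, which passed over the initiation factors alone (adjusted p = 0.0208).

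For the lower cytosolic synthetase list, the median of all features, 0.0013, decides nothing about a shift between arrays, because normalisation had already set the array medians close together. A decline of all tRNA synthetases is argued against by the 8 cytosolic ones that did not pass over the list alone. These 8 stood at 90.9% to 105% of control, with control means of 6.31 to 9.32. Vars, Farsa, Qars and Wars, at 6.31 to 6.80, were dimmer than all 8 lower ones, at 7.02 to 10.1. Hars and Farsb had intervals of -0.37 to 0.18 and -0.30 to 0.03, which allow a smaller fall. The mitochondrial median was 0.0047, the mean shifts of the 2 lists differing by -0.31 ± 0.02 (SE). The mitochondrial genes were dimmer, averaging 6.28 in controls against 7.80 for the cytosolic list, so compressed fold changes are not excluded there. A change in the mix of cell types stays open: the largest median shift of a marker list was 0.082, for erythroid cells, which became 0.28 without control mouse 1, as large in size as the synthetase shift, and -0.0025 without control mouse 3. With all 6 mice, 7 of the 9 marker lists shifted by less than the synthetases by over 2 SE. The erythroid and tendon lists, of 3 and 4 genes, were too variable to decide. The comparison was of sizes only, and the medians of these 2 lists were rises where the synthetases fell. Fast fibre genes, with a median of 0.022, gave no sign of a fall of fibre mRNAs in general. The 10 splits of the 6 mice are too few to give a share under 0.05. The real split alone (1 of 10) gave a median shift as large as 0.27, the highest other being 0.15. The other splits keep part of any genotype difference, so they are no null background. Loss of ATF4 in muscle, the difference the design names, stays open and was not tested apart from other differences between these 6 mice; further littermates of both genotypes would test it.

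That transporters and amino acid synthesis genes shifted less than synthetases might come from low signal that compresses fold changes. The 11 members above the median level of all features had a median of -0.069, and the mean shift of the synthetases lay 0.20 below theirs (difference -0.20 ± 0.03, SE). This does not decide the question, because some of the 11 were still dimmer than the 8 lower synthetases. Slc6a9, Mthfd2 and Shmt2 had control means of 6.05, 6.07 and 6.12, against 7.02 to 10.1 for those 8. Slc7a6, Gpt2, Slc38a2 and Got1, with control means of 7.19 to 10.7, had 0.05, -0.23, -0.34 and -0.04. Within these 11, Mthfd2 and Slc38a2 had -0.35 and -0.34, so the members were not alike. No biological explanation of the difference was tested.

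Nol12 lies 30 measured genes from Atf4 on the same chromosome, which made a carried-over segment beside the targeted locus a candidate explanation for its lower signal. Of the 99 other genes among the nearest 50 on each side, 2, or 2.02%, had an unadjusted p under 0.05, against 2.85% of the other named features (two-sided Fisher's exact p = 1.00). Both were higher in ATF4 mKO, unlike Nol12: Tbrg3, 38 measured genes from Atf4 and 1 of the 10 genes named in the higher direction, with 0.38 ± 0.08 (SE), and Cby1, 12 genes away and named after its value was seen, with 0.33 ± 0.11 (SE). The 95% exact binomial interval of 0.246% to 7.11% leaves an effect on few genes open. Chance among dim features is also open. In 8 of the other 9 splits of the mice a feature below the median level reached a limma p as small as that of Nol12. The smallest was 6.08e-06. With so many dim features tested, such a p was likely in any split, so the splits do not decide this.

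The 10 splits are also too few for the counts: the real split called 2 features (1 of 10 splits as large), and the highest other called 0. For the lists, 2 of the 10 splits called 5 or more, the real one with 5 and the split of control mice 1 and 2 with ATF4 mKO mouse 2 against the rest with 6. At an unadjusted p under 0.05 the real split had 518 features and the others 530 to 1414; the 1414 belonged to the split with 6 lists.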
